A study of Mus musculus with 18 samples.

How the data were processed

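The study measured total RNA of mouse bone marrow stromal cell clones on Affymetrix oligonucleotide arrays of 3 chip types, MG_U74Av2, MG_U74Bv2 and MG_U74Cv2, each of which carries a different set of probe sets. Per the labels' protocols, clones were grown from single cells in DMEM with fetal bovine serum, RNA was prepared with RNeasy columns and labelled with biotin, and purity was estimated by flow cytometry for CD34. The labels name other bone marrow cells as the possible contaminant. There were 6 RNAs, 3 from CD34+ clones and 3 from CD34- clones, and each was hybridised to 1 array of every chip type, which gave 18 arrays. Groups and replicate numbers were taken from the sample titles.

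The deposited values are linear signal intensities per probe set, made with MAS5 per the submitters' processing notes. The MAS5 version and settings are not given in the sources used here. Detection calls were not used here, and dim probe sets were removed by the filter described below alone. MAS5 commonly scales each array to a common trimmed mean. The CD34+ arrays had been brought to such a target, with a mean, trimmed by 2% at each end, of 1500 to 1501, while the CD34- arrays had not. The CD34- arrays lay below by a factor of 14.1 to 19.5 on MG_U74Av2, 45.0 to 55.9 on MG_U74Bv2 and 83.7 to 120 on MG_U74Cv2. The deposited intensities of the groups were therefore not comparable as they stood. Arrays have no read depth, and the number of arrays limits the precision.

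Main design, alternatives, named-gene rule and gene lists were fixed before the data were examined. Deposited values were to be used as they stood where the trimmed means of a chip type agreed within 5%, and to be quantile normalized otherwise. They did not agree on any chip type, so the 6 arrays of each chip type were quantile normalized with limma. The 20th percentile of the normalized values of the chip type (51.5 for MG_U74Av2, 106 for MG_U74Bv2 and 97.9 for MG_U74Cv2) was added before log2 was taken. A fold change is therefore on the log2(value + offset) scale, which understates the change of dim probe sets. The 66 control probe sets of each chip type were left out. A probe set was tested where its deposited value lay above the 40th percentile of its own array on at least 3 of 6 arrays. That left 7634 probe sets on MG_U74Av2 and removed 4788, with 7737 left and 4674 removed on MG_U74Bv2, and 7481 left and 4387 removed on MG_U74Cv2.

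Each chip type was fitted on its own with limma (lmFit, then eBayes with an intensity trend), with the group as the only term and CD34+ minus CD34- as the direction. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within the chip type, and a probe set was called at an adjusted p under 0.05. Nothing in the labels says that the 3 RNAs of a group came from separate cultures or animals, and the series' design text speaks of 2 samples. The p-values then measure only the spread between these RNAs, which may be technical. If each group was 1 clone, a difference between the clones cannot be told apart from one of CD34 status. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used.

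Gene symbols came from GEO's platform annotation. Of the probe sets, 10833 had 1 gene symbol, 396 several and 1193 none on MG_U74Av2. The same counts were 10581, 178 and 1652 on MG_U74Bv2, and 7717, 150 and 4001 on MG_U74Cv2. Symbols were matched through their Entrez identifier to the RefSeq gene table of GRCm38.p6 for 10817, 10550 and 7677 probe sets on the 3 chip types, and 0 were renamed. That table was used for names alone. The array files name no genome build, so positions are not given. Probe sets with several genes were named after none.

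For gene lists, each gene was represented by 1 probe set, from the first chip type in the order A, B, C with a tested probe set for it, and there the one with the highest mean. The 11969 genes so obtained were tested with limma's camera at a preset correlation between genes of 0.01, over 28 lists with at least 5 tested members, with adjustment over the lists. Camera with an estimated correlation and limma's fry were alternatives. The lists of cell type markers were mesenchymal stromal surface, pericyte, haematopoietic stem and progenitor, macrophage and myeloid, neutrophil granule, lymphoid, erythroid, endothelial, osteoblast, adipocyte, chondrocyte, smooth muscle and contractile, skeletal muscle, neural and epithelial. The pathway lists were haematopoiesis-supporting secreted factors, chemokines and inflammatory mediators, interferon response, antigen presentation, cell cycle, extracellular matrix, matrix proteases and inhibitors, TGF-beta and BMP, Wnt, Hox, imprinted, cholesterol synthesis, glycolysis and hypoxia, p53 target and senescence, and unfolded protein and stress response genes. Sex-linked and reference genes were controls outside the list test.

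The rule for named genes took Cd34, the controls, the 10 genes with the largest rise and the 10 with the largest fall on MG_U74Av2, and 4 each way on the other chip types. These had to be called, separated between the groups, brighter than the median of the chip type in the higher group and named by 1 symbol that is not a clone name. The rule spoke of the mean deposited value, but deposited values of the groups were on different scales, so the normalized mean was used. From each list it took up to 4 called members with the largest fold, or the member with the smallest p. Any other gene or probe set was named after its values were seen, and the text says so.

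The instrument settings saved with each array, per the file headers, gave the chip type, the fluidics station and the scan day. Each chip type was scanned on 1 day with chips of 1 lot. On MG_U74Av2, station 1 held 1 array of each group and station 2 held 2 of each. On the other chip types station 1 held 3 CD34+ arrays and 1 CD34- array, and station 2 held 2 CD34- arrays. The station was therefore run as a block and, where a station held both groups, within it.

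Alternatives were: deposited values without scaling, deposited values centred on each array's median log2 value, no filter and a filter at the 60th percentile, an offset of 0.25 and 4 times the main offset, eBayes without a trend and with a robust trend, the replicate number as a block, a threshold of at least 2-fold, leaving out each RNA in turn, other probe sets of a gene, the mean of all probe sets of a gene, and MG_U74Av2 alone. Scaling each array to a common median before the offset, scaling to a common trimmed mean, and the station block were added after seeing the data. Leave-outs kept the scale and the filter set on all 6 arrays.

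The fits were tested on simulated data with 200 changed probe sets per chip type. At a 2-fold change 70.1% were recovered on MG_U74Av2, 41.8% on MG_U74Bv2 and 17.9% on MG_U74Cv2, and at 4-fold 100%, 97.0% and 81.8%. Of 143 calls on MG_U74Av2, 5 were false, as were 3 of 102 on MG_U74Bv2 and 3 of 70 on MG_U74Cv2. Of 51 simulated lists of 25 genes, the list test called the 1 raised list and 0 of the unchanged ones. The simulated genes varied independently of each other, whereas the estimated correlation reached 0.53 for the interferon list. The simulation therefore gives no error rate for lists of correlated genes.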

Results

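Gene expression was measured in bone marrow stromal cells of the mouse, adherent fibroblast-like cells of the marrow. The cells had been isolated from adult marrow by CD34, a surface sialomucin best known from blood stem cells and endothelium, and grown as colonies from single cells. Of 6 RNAs, 3 came from CD34+ clones and 3 from CD34- clones, and each RNA was read on 3 chip types, MG_U74Av2, MG_U74Bv2 and MG_U74Cv2, so that 18 arrays were compared. The labels do not say whether the RNAs of a group came from separate clones. A difference between single clones therefore cannot be told apart from one of CD34 status. The labels name a comparison with normal marrow stromal cells as the purpose. Those cells are not analysed here, and the comparison made was CD34+ against CD34- clones. The deposited signals of the groups were on different scales, and all levels given below are quantile-normalized signals in intensity units (mean ± SD, n = 3 RNAs per group). The number of arrays limits the precision.

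**Figure D1:**
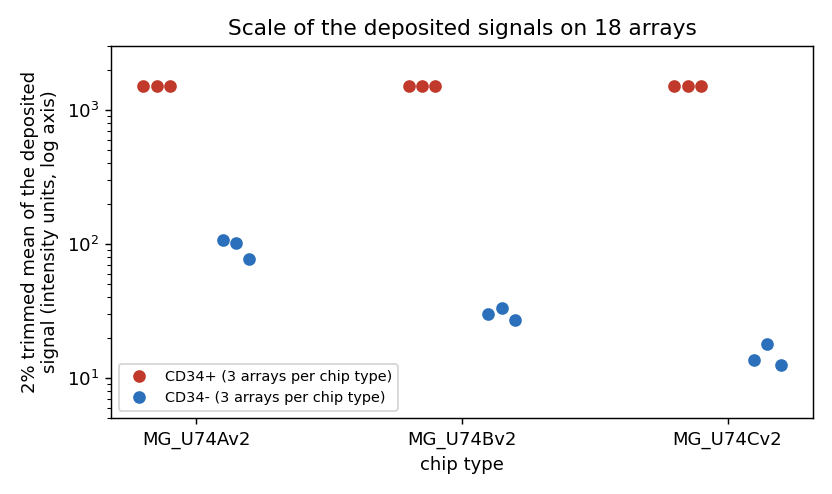
Trimmed mean of the deposited signal of each of the 18 arrays (intensity units, log axis) by chip type, with CD34+ arrays in red and CD34- arrays in blue. CD34+ arrays lie at 1500 or 1501 on every chip type, while CD34- arrays lie at 76.9 to 107 on MG_U74Av2, 26.8 to 33.4 on MG_U74Bv2 and 12.5 to 17.9 on MG_U74Cv2.

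Cd34 itself was higher in the CD34+ clones. Its brighter probe set in CD34+ clones read 881 ± 82.0 in CD34+ clones against 120 ± 56.3 in CD34- clones, a 5.65-fold difference (limma adjusted p = 0.000374). Another probe set read 870 ± 48.3 against 131 ± 62.5 (log2 difference 2.39, limma adjusted p = 0.000334). All 3 CD34+ RNAs lay above all 3 CD34- RNAs for each probe set, and the exact permutation p was 0.1, the smallest that 3 against 3 RNAs can give. Xist, which is transcribed from the inactive X chromosome of females, read 198 ± 39.5 against 227 ± 30.7 (log2 -0.17, limma adjusted p = 0.652) and was the only sex-linked gene tested, so the groups did not differ in it beyond the spread. Of 8 reference genes, which are often used to scale expression data, 2 rose, 1 fell and 5 did not pass the test, and the counts were the same adjusted over the list alone. Pgk1, a glycolytic kinase, rose by 0.63 on the log2 scale (adjusted p = 0.00105), Hprt, a purine salvage enzyme, rose by 0.47 and B2m, the light chain of class I major histocompatibility molecules, fell by 0.69 (adjusted p = 0.00464). Relative to the median of all probe sets, these 3 moved the same way under every scaling tried.

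On MG_U74Av2, Gatm, which makes the precursor of creatine, had the largest rise among named genes, from 134 ± 23.9 in CD34- clones to 1423 ± 6.0 in CD34+ clones (8.01-fold, adjusted p = 1.14e-05). Rtn2, a reticulon of the endoplasmic reticulum, rose by 2.47 on the log2 scale, Ankrd1, an ankyrin repeat protein of muscle and stretched cells, by 2.34, and the secreted axon guidance factors Sema3c and Sema3e by 2.29 and 2.18. Krt19, a keratin of simple epithelia, rose by 2.17 at 1 probe set and 1.57 at another, and Id2, an inhibitor of helix-loop-helix transcription factors, by 2.04. Marcksl1, an actin-binding substrate of protein kinase C, rose by 2.01, and Fmc1, an assembly factor of the mitochondrial ATP synthase, by 2.02, although its CD34- RNAs scattered (295 ± 248) and a brighter probe set rose by only 0.41 (adjusted p = 0.0187). A probe set with no single gene symbol rose more than any of these (log2 4.00) and was picked out after its values were seen.

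Fos, a subunit of the AP-1 transcription factor, had the largest fall among named genes on MG_U74Av2, from 2382 ± 1016 in CD34- clones to 178 ± 24.6 in CD34+ clones (10.1-fold, adjusted p = 0.000128). The matricellular protein Ccn3 fell from 2283 ± 91.2 to 249 ± 21.7 (log2 -2.96, adjusted p = 5.14e-06), and its relative Ccn5 fell by 2.21 on the log2 scale. Pltp, which moves phospholipids between lipoproteins, fell by 2.45, as did Aldh1a2, which makes retinoic acid (log2 -2.41), and Ctsk, a collagen-cutting cathepsin of osteoclasts and fibroblasts (log2 -2.38). On MG_U74Cv2, Ctsk differed by log2 -0.56 (adjusted p = 0.707), and 2 further probe sets of Aldh1a2 by log2 0.11 each (adjusted p = 0.968 and 0.935). Col3a1, the chain of type III collagen, fell at 3 probe sets (log2 -1.99, -1.81 and -1.70), as did Cox6a2, a muscle isoform of a cytochrome c oxidase subunit (log2 -1.80), Marcks (log2 -1.78) and the secreted ribonuclease Rnase4 (log2 -1.77). On MG_U74Bv2 the groups overlapped at each probe set of Marcks. Each of these named genes of MG_U74Av2 kept its call when any 1 RNA was left out.

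In all, 1138 of 7634 probe sets were called on MG_U74Av2, of which 627 rose and 511 fell, and they named 951 genes. Of these, 209 differed at least 2-fold, 87 upward and 122 downward. The groups did not overlap in 34.5% of the tested probe sets, against 10% by chance. Arrays correlated at 0.956 to 0.9745 within groups and 0.931 to 0.947 between them. The count fell to 717 without CD34+ RNA 1, 634 without CD34+ RNA 2, 740 without CD34+ RNA 3 and 730 without CD34- RNA 1. Each fluidics station, the machine that washes and stains the arrays, held both groups on this chip type: with the station as a block 986 probe sets were called. Within station 2 (2 against 2 arrays) 829 were called, of which 718 (86.6%) had the same sign in station 1 (1 against 1 array, with no test), against 63.6% of all tested probe sets, a split of the arrays chosen after seeing the data. The deposited values without any scaling would call 7630 probe sets as higher and 0 as lower, with a median shift of 3.70 on the log2 scale. Centred on each array's median log2 value, they would call 1045 as higher and 758 as lower.

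**Figure D2:**
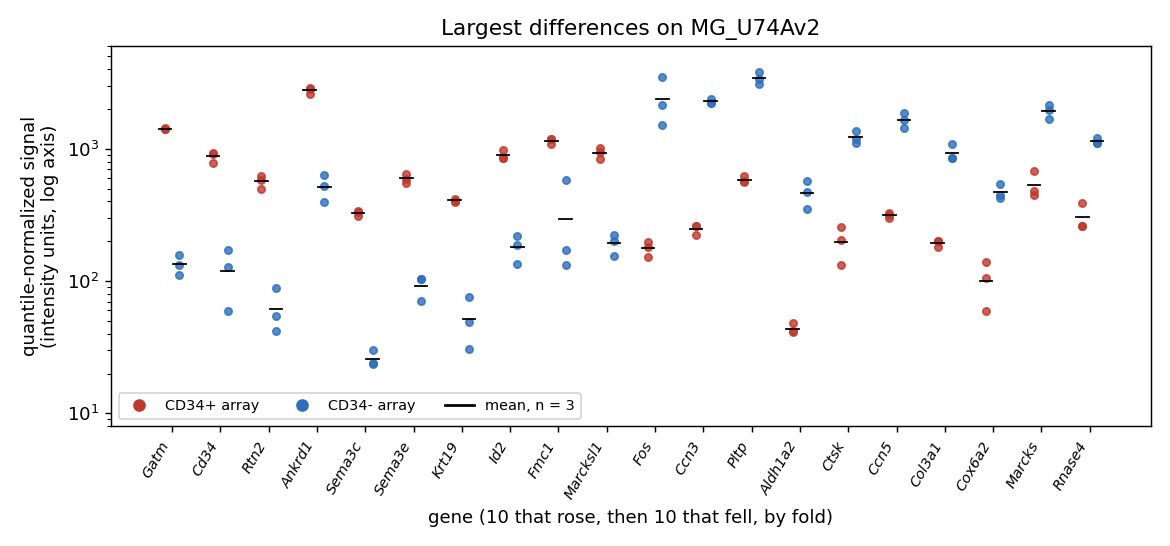
Quantile-normalized signal (intensity units, log axis) of the 10 named genes that rose most and the 10 that fell most on MG_U74Av2, with a point for each array, red for CD34+ and blue for CD34-, and a line at the mean of 3. Gatm lies at 1423 in CD34+ clones against 134 in CD34- clones, and Fos at 178 against 2382.

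**Figure D3:**
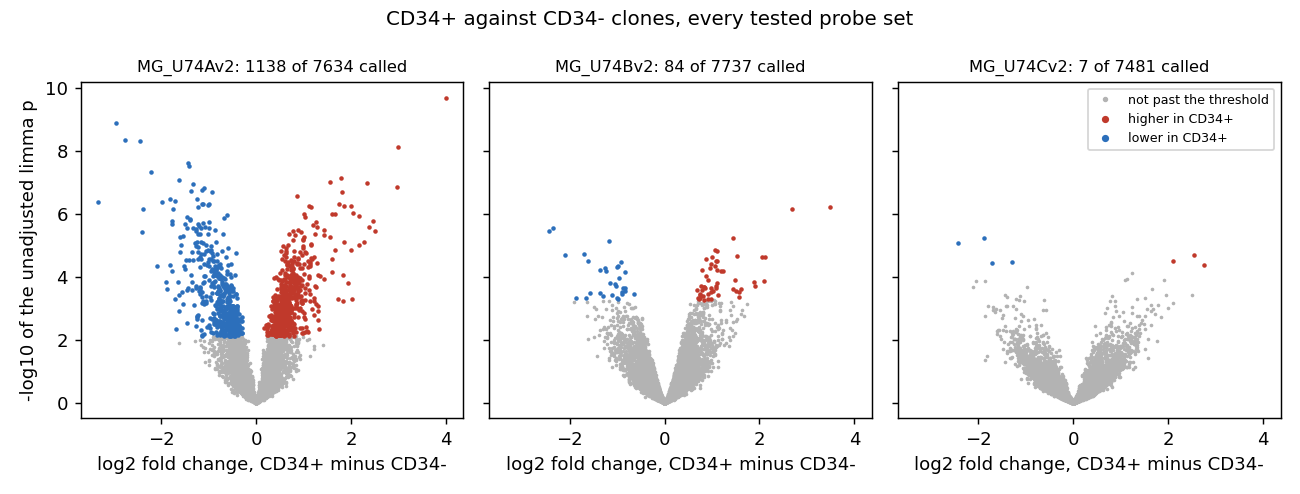
Log2 fold change (CD34+ minus CD34-) against -log10 of the unadjusted limma p for every tested probe set of the 3 chip types, red where higher and blue where lower in CD34+ clones at an adjusted p under 0.05. The called probe sets number 1138 on MG_U74Av2, 84 on MG_U74Bv2 and 7 on MG_U74Cv2.

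On MG_U74Bv2, a further probe set of Gatm rose from 103 ± 75.0 to 2150 ± 238 (log2 3.49, adjusted p = 0.00278), and Celf4, an RNA-binding splicing regulator, from 183 ± 44.2 to 1756 ± 305 (log2 2.68, adjusted p = 0.00278). Poc1a, a centriole protein, rose by 2.11 and Slc25a13, a mitochondrial aspartate and glutamate carrier, by 2.09. Itga11, a subunit of a collagen-binding integrin, fell from 1234 ± 222 to 142 ± 38.8 (log2 -2.43, adjusted p = 0.00685), and Epas1, a hypoxia-inducible transcription factor, from 2148 ± 234 to 344 ± 119 (log2 -2.36). Igsf5, an immunoglobulin-like junction protein, fell by 2.09 and C1s1, a protease of the complement system, fell by 1.70. Of 7737 probe sets tested, 84 were called, 53 up and 31 down, and 48 differed at least 2-fold. The groups did not overlap in 23% of the tested probe sets, against 10% by chance. Deposited values without scaling called 7737 up and 0 down (median shift 5.22), and centred on each array's median log2 value 378 up and 82 down. Without a filter 37 probe sets were called, and without a variance trend 16.

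Leaving out any RNA but CD34- RNA 2 moved the calls on MG_U74Bv2: 4 probe sets were called without CD34+ RNA 1 (Gatm, Celf4, Itga11 and Epas1), 5 without CD34+ RNA 2 (these 4 and a probe set with no gene symbol), 6 without CD34+ RNA 3, 2 without CD34- RNA 1 (Gatm and Celf4) and 54 without CD34- RNA 3. Without CD34- RNA 1, Itga11 and Epas1 had an adjusted p of 0.0592 each. Poc1a, Igsf5 and C1s1 lost their call without CD34- RNA 1 or any 1 CD34+ RNA (adjusted p up to 0.0844, 0.0768 and 0.0844), and Slc25a13 without any RNA other than CD34- RNA 2 (up to 0.136). With the station as a block only Mfsd4b5, picked out after its values were seen, was called (log2 2.35, adjusted p = 0.0194). Within station 1, which held 3 CD34+ arrays and 1 CD34- array, Gatm, Mfsd4b5 and Met were called, the last 2 also named after their values were seen. Station 2 held 2 CD34- arrays and no CD34+ array.

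On MG_U74Cv2, Tusc1, a tumour suppressor candidate, rose from 124 ± 65.1 to 1426 ± 486 (log2 2.77, adjusted p = 0.0456) and a further probe set of Celf4 from 308 ± 14.5 to 1666 ± 369 (log2 2.10). Itgbl1, a secreted integrin-like protein, fell from 2131 ± 511 to 310 ± 29.5 (log2 -2.43, adjusted p = 0.0319), Fam180a fell by 1.71 and Amhr2, the receptor of anti-Müllerian hormone, fell by 1.29. The fall of Amhr2 rests on 1 probe set, which read 5031 to 16100. Its further probe sets on this chip type, removed by the filter, read 83.2 to 245 with overlapping groups. With 2 probe sets with no single gene symbol (log2 2.56 and -1.87), picked out after their values were seen, the probe sets called for Tusc1, Celf4, Itgbl1, Fam180a and Amhr2 were all 7 called of 7481 tested, against 661 at an unadjusted p under 0.05. The groups did not overlap in 14.1% of the tested probe sets, against 10% by chance. Without any 1 RNA all 7 lost their call, with adjusted p from 0.0579 to 0.291 in the 6 leave-outs. With the station as a block 0 were called by limma (471 at an unadjusted p under 0.05), and within station 1 (3 against 1 array) only a probe set with no single gene symbol, seen afterwards, was called (adjusted p = 0.00909). That probe set was also the only call without CD34- RNA 3 (adjusted p = 0.00325). Deposited values without scaling called 7481 up and 0 down (median shift 6.30), and centred on each array's median log2 value 0 up and 2 down, Itgbl1 and the unnamed probe set that fell.

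Signs of RNA quality and the RNA concentration moved with the groups on MG_U74Av2, and so with each gene group described next. The ratio of 3' to 5' signal was 0.747 ± 0.0406 in CD34+ RNAs against 0.818 ± 0.0148 in CD34- RNAs for Gapdh and 1.07 ± 0.0311 against 1.15 ± 0.05 for actin, without overlap, and the RNA concentrations in the labels were 0.421 to 0.721 against 0.989 to 1.38 µg/µl. The volumes in the labels moved the opposite way (20.8 to 35.6 µl against 10.8 to 15.1 µl), so the concentrations do not show a difference in RNA amount. The Gapdh ratios of the same RNAs overlapped on the other chip types (0.803 against 0.792 on MG_U74Bv2 and 0.778 against 0.776 on MG_U74Cv2). The actin ratios overlapped on MG_U74Bv2 (1.089 against 1.101) but not on MG_U74Cv2 (0.977 against 1.027). A difference in RNA quality is therefore not seen on every chip type.

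Genes of the extracellular matrix were lower in CD34+ clones. In this and the other lists, where 5 or fewer members passed, all are named; those beyond the 4 with the largest fold, and those past the threshold only when adjusted over the list alone, were named after their values were seen. Of 28 measured, 15 fell, 1 rose and 12 did not pass the test, and adjusted over the list alone 19 fell and 1 rose (median log2 difference -0.62, camera adjusted p = 3.77e-16). Col1a1, the main chain of type I collagen, went from 42620 ± 2455 to 19940 ± 1771 (log2 -1.10, adjusted p = 8.05e-05), Postn, a matricellular protein of periosteum, from 20670 ± 1917 to 9387 ± 344 (log2 -1.13), and Ogn, a small leucine-rich proteoglycan, fell by 1.23. Tnc, tenascin C, was the member that rose, by 0.76 (adjusted p = 0.00163). The list kept its call with an estimated correlation (adjusted p = 0.0389), and relative to the median of all genes its median was -0.38 in the deposited values. Its mean log2 difference was -0.64 within station 1 and -0.60 within station 2 on MG_U74Av2.

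Matrix proteases and their inhibitors were lower too: 8 of 16 fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose (median log2 difference -0.81, camera adjusted p = 1.49e-06, and adjusted p = 0.0442 with an estimated correlation). Ctsk, named above, was followed by Timp3, an inhibitor of metalloproteinases (log2 -1.28), Mmp13, a collagenase (log2 -1.13, adjusted p = 0.0227), and Serpinf1, a secreted antiangiogenic serpin (log2 -1.12). Mmp13 lost its call without CD34+ RNA 1 (adjusted p = 0.0709), CD34+ RNA 3 (0.0696), CD34- RNA 1 (0.0941) or CD34- RNA 3 (0.0603). Plaur, the urokinase receptor, rose by 0.84 (adjusted p = 0.00821). Among smooth muscle and contractile genes 7 of 17 fell and 0 rose, and adjusted over the list alone 8 fell and Cald1 and Actn1 rose (median log2 difference -0.28, camera adjusted p = 0.00151, but adjusted p = 0.322 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, went from 10880 ± 676 to 4332 ± 362 (log2 -1.32, adjusted p = 6.67e-05), and Cnn1, calponin (log2 -1.22), and the actins Actg2 and Acta2 (log2 -0.53 and -0.44) fell too, but Acta2 lost its call with centred deposited values (log2 -0.19, adjusted p = 0.291), with arrays scaled to a common median (0.105) or trimmed mean (0.0589) and without a variance trend (0.0746). The smooth muscle call was also lost with deposited values centred on each array's median (adjusted p = 0.28) and with the mean of a gene's probe sets (0.222). In centred deposited values the offset raises bright probe sets in CD34+ clones, which shrinks falls of bright genes. Mean log2 differences within stations 1 and 2 were -0.78 and -0.68 for the proteases and -0.39 and -0.39 for the smooth muscle genes.

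Cell cycle genes were higher in CD34+ clones. Of 29 measured, 12 rose and 0 fell, and adjusted over the list alone 16 rose (median log2 difference 0.43, camera adjusted p = 6.80e-08, and adjusted p = 0.0389 with an estimated correlation). Cdc20, which activates the ubiquitin ligase of anaphase, went from 3035 ± 200 to 5414 ± 62.0 (log2 0.83, adjusted p = 0.000446), Bub1, a spindle checkpoint kinase, rose by 1.17, Rrm2, a subunit of ribonucleotide reductase, by 1.05 and Aurka, a mitotic kinase, by 0.84. Among targets of p53 and senescence genes 3 of 17 fell and 0 rose, and adjusted over the list alone 4 fell, these and the antiproliferative Btg2 (median log2 difference -0.15, camera adjusted p = 0.0351, and adjusted p = 0.417 with an estimated correlation). The 3 were Gadd45a, a stress protein (log2 -1.46), Plk2, a polo-like kinase (log2 -0.76), and Cdkn2b, an inhibitor of CDK4 and CDK6 (log2 -0.47). Cdkn2b was called only with all RNAs or without CD34- RNA 2 or 3 (adjusted p up to 0.0989 otherwise). The p53 list lost its call without CD34+ RNA 1 (adjusted p = 0.135), CD34- RNA 1 (0.0961) or CD34- RNA 3 (0.0799), without a filter (0.0586), with centred deposited values (0.0989), the mean of a gene's probe sets (0.0602) or fry (0.0715), and on MG_U74Av2 alone, with the station as a block or without (0.158 and 0.156). Mean log2 differences within stations 1 and 2 were 0.47 and 0.45 for cell cycle genes and -0.14 and -0.23 for the p53 list.

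Enzymes of cholesterol synthesis were higher in CD34+ clones, with 8 of 17 rising, 0 falling and, adjusted over the list alone, 11 rising (median log2 difference 0.55, camera adjusted p = 1.49e-06, and adjusted p = 0.0442 with an estimated correlation). Fdps, which makes farnesyl pyrophosphate, went from 5218 ± 387 to 11820 ± 1233 (log2 1.17, adjusted p = 0.000133), and Idi1, an isomerase upstream of it, rose by 1.04. Of 23 glycolysis and hypoxia genes 7 rose and 2 fell, and adjusted over the list alone 8 rose and 3 fell, Ero1a in addition (median log2 difference 0.28, camera adjusted p = 0.0183, and adjusted p = 0.196 with an estimated correlation). The glycolytic enzymes Ldha, Pgk1 and Pgam1 rose by 0.69, 0.63 and 0.62. The members that fell were Ndrg1, a stress-responsive gene induced by hypoxia (log2 -1.11), and P4ha1, a collagen prolyl hydroxylase (log2 -0.42), and P4ha1 was called only with all RNAs or without CD34- RNA 2 (adjusted p up to 0.124 otherwise). On MG_U74Av2 alone the glycolysis list had an adjusted p of 0.0471, and of 0.0514 with the station as a block as well. Mean log2 differences within stations 1 and 2 were 0.42 and 0.57 for cholesterol synthesis and 0.08 and 0.24 for glycolysis.

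Interferon response genes were lower in CD34+ clones. Of 26 measured 6 fell and 0 rose, and adjusted over the list alone 15 fell (median log2 difference -0.61, camera adjusted p = 6.80e-08), but the call was lost with an estimated correlation (adjusted p = 0.45) and with fry (0.0954). Mx2, an antiviral GTPase, fell by 1.13, and Ifi27l2a (log2 -1.12), Ifit3 (log2 -1.10) and Ifi35 (log2 -0.95) fell too. Ifit3 had overlapping groups (2211 ± 1207 against 4448 ± 900.2) and lost its call without CD34+ RNA 1 (adjusted p = 0.121), CD34+ RNA 2 (0.135), CD34- RNA 1 (0.136) or CD34- RNA 3 (0.0908). RNAs of a group differed in this list: its mean over members was -0.38, -0.46 and 0.05 in the CD34+ RNAs and 0.47, 0.05 and 0.28 in the CD34- RNAs, on the log2 scale around each gene's mean. Antigen presentation genes were lower as well, with 5 of 14 falling, 0 rising and, adjusted over the list alone, 6 falling (median log2 difference -0.57, camera adjusted p = 8.53e-05, but adjusted p = 0.41 with an estimated correlation and 0.0624 with fry). These were H2-D1 and H2-K1, heavy chains of class I molecules (log2 -1.18 and -1.10), Tapbp, which loads them with peptide (log2 -1.17, but -0.32 with an adjusted p of 0.116 at another probe set), Cd74, the invariant chain of class II molecules (log2 -0.92), and Psmb10, an immunoproteasome subunit (log2 -0.62). Cd74 lost its call without CD34+ RNA 1 (adjusted p = 0.0525), CD34+ RNA 2 (0.0639) or CD34- RNA 2 (0.0577). Markers of macrophages, neutrophils, lymphoid and erythroid cells, 24 genes tested, had a median log2 difference of -0.06, and 0 were called by limma and 0 had an unadjusted p under 0.05. In the deposited values centred on each array's median log2 value, however, their median was -0.32 relative to all genes, 9 had an unadjusted p under 0.05 and the lymphoid list was called lower (camera adjusted p = 0.0475). Without the filter as well, the median was -0.67 for these markers and -0.01 for the interferon list. In both of these settings the offset weighed more on the CD34- arrays, which lowers dim probe sets in CD34+ clones. With arrays scaled to a common median or trimmed mean, the markers lay at -0.075 and -0.072 and the interferon list at -0.614 in both. In quantile-normalized values without the filter these medians were -0.084 and -0.596.

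Chemokines and inflammatory mediators were lower in CD34+ clones, with 5 of 11 falling, 1 rising and, adjusted over the list alone, 6 falling and 1 rising (median log2 difference -0.48, camera adjusted p = 0.0183, and adjusted p = 0.566 with an estimated correlation). Il1rn, the antagonist of the interleukin-1 receptor, fell by 1.60, and the chemokines Cx3cl1, Ccl7, Ccl2 and Ccl9 fell (log2 -0.91, -0.82, -0.66 and -0.48), while Ptgs2, the inducible prostaglandin synthase, rose by 0.86. Another probe set of Cx3cl1 on MG_U74Av2 differed by log2 -0.04 (adjusted p = 0.97). Ccl2 lost its call without CD34+ RNA 1 (adjusted p = 0.0504) or CD34+ RNA 2 (0.0513), Ccl9 without CD34+ RNA 1 (0.0689), CD34+ RNA 2 (0.0799) or CD34- RNA 1 (0.0717), and Ccl7 without any RNA other than CD34- RNA 2 (up to 0.095). The list lost its call without CD34+ RNA 1 (0.0561) or CD34- RNA 1 (0.0961), without a filter (0.163) and with fry (0.0971). Mean log2 differences within stations 1 and 2 were -0.70 and -0.48 for interferon response, -0.75 and -0.58 for antigen presentation and -0.49 and -0.34 for chemokines.

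**Figure D4:**
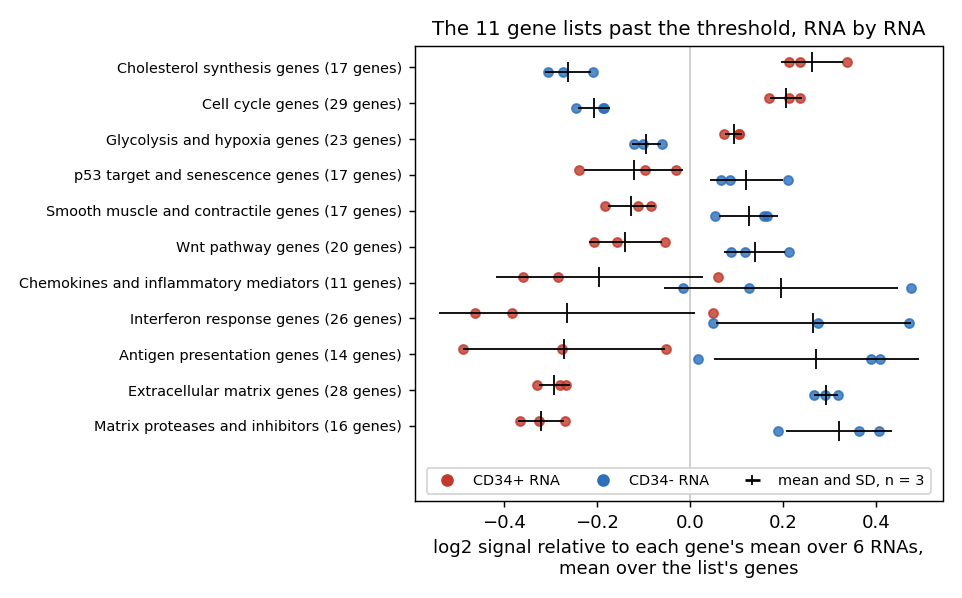
Mean log2 signal over the genes of each of the 11 gene lists past the threshold, relative to each gene's mean over 6 RNAs, with a point for each RNA, red for CD34+ and blue for CD34-, and bars for the group's mean and SD (n = 3). Extracellular matrix genes lie at -0.29 ± 0.033 against 0.29 ± 0.026, whereas interferon response genes scatter (-0.27 ± 0.275 against 0.27 ± 0.21).

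Of 20 Wnt pathway genes 4 fell and 1 rose, and adjusted over the list alone 6 fell and 1 rose (median log2 difference -0.22, camera adjusted p = 0.0191, and adjusted p = 0.196 with an estimated correlation). Ccn5 fell by 2.21, as did the receptor Fzd1 (log2 -1.20), Ctnnb1, beta-catenin (log2 -0.48), and Ccn4 (log2 -0.46), whereas Sfrp2, a secreted Wnt modulator, rose by 1.66 (adjusted p = 0.000197). Ccn4 lost its call without CD34+ RNA 1 (adjusted p = 0.0523) or CD34+ RNA 2 (0.0558), Ctnnb1 with centred deposited values (log2 -0.30, adjusted p = 0.0927) or without a variance trend (0.0577), and the list without CD34+ RNA 3 (0.0523), without a filter (0.0586) and on MG_U74Av2 alone, with the station as a block or without (0.12 and 0.114). Mean log2 differences of the list within stations 1 and 2 were -0.16 and -0.24.

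In the TGF-beta and BMP list 5 of 26 rose and 0 fell, and adjusted over the list alone 5 rose and the ligands Tgfb2 and Tgfb3 fell. As a list it was not called (camera adjusted p = 0.654), with a median of -0.01, a mean of 0.17 and an upward test. The members that rose were Id2, Id1 and Id3, inhibitors of helix-loop-helix factors (log2 2.04, 0.89 and 0.51), Tgfbi, a secreted matrix protein (log2 1.44), and Inhba, the activin A subunit (log2 1.13). Id3 was called only with all RNAs or without CD34+ RNA 2 or CD34- RNA 3 (adjusted p up to 0.109 otherwise). Of 12 imprinted genes Ndn, a growth suppressor, and Igf2, a fetal growth factor, rose (log2 1.93 and 1.06) and 0 fell, as adjusted over the list alone (list adjusted p = 1, median -0.02, mean 0.18, test up, but down in centred deposited values). Igf2 was called only with all RNAs or without CD34- RNA 2 (adjusted p up to 0.105 otherwise). Of 15 Hox genes only Hoxa9 was called, upward (log2 0.72), as it was adjusted over the list alone (list adjusted p = 0.834, median -0.01, mean 0.01, test up, but down in centred deposited values). Without any 1 CD34+ RNA or CD34- RNA 1, Hoxa9 was not called (adjusted p up to 0.0896).

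Of 20 unfolded protein and stress response genes 2 rose and 5 fell, the same as adjusted over the list alone, and the list was not called (camera adjusted p = 0.41). The chaperones Hsph1 and Hsp90b1 rose by 0.54 and 0.38. Those that fell were Trib3, a pseudokinase (log2 -0.83), Hmox1, heme oxygenase (log2 -0.69), Ddit3, a transcription factor of the stress response (log2 -0.58), the chaperone Hspa1b (log2 -0.44) and Herpud1, of protein degradation at the endoplasmic reticulum (log2 -0.38). Hsp90b1 lost its call without CD34+ RNA 1 (adjusted p = 0.0507), Hmox1 without CD34+ RNA 2 (0.0622) or CD34- RNA 1 (0.0605), and Ddit3 without CD34+ RNA 1 (0.0727), CD34+ RNA 2 (0.0883) or CD34- RNA 2 (0.0535). Hspa1b was called only with all RNAs or without CD34+ RNA 3 or CD34- RNA 1 (adjusted p up to 0.101 otherwise), and Herpud1 only with all RNAs or without CD34- RNA 2 (up to 0.124).

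Surface markers of mesenchymal stromal cells moved both ways: of 15 measured 3 rose and 4 fell, and adjusted over the list alone 4 rose and 5 fell, Alcam and Pdgfrb in addition (camera adjusted p = 0.253). Cd47, which inhibits phagocytosis, fell from 3486 ± 515 to 1282 ± 116 (log2 -1.40, adjusted p = 0.000248), Pdgfra, a receptor of platelet-derived growth factor, fell by 1.16 at 1 probe set (log2 -0.46, adjusted p = 0.664 at another), and the integrin chain Itgb1 (log2 -0.43) and Eng, endoglin (log2 -0.42), fell too. Nes, nestin, rose by 0.98, Cd44, the hyaluronan receptor, by 0.50 and the tetraspanin Cd9 by 0.38. Itgb1 lost its call without CD34+ RNA 3 (adjusted p = 0.0612), Eng without CD34+ RNA 1 (0.0657), CD34+ RNA 2 (0.102) or CD34- RNA 1 (0.0877), and Cd44 and Cd9 without any RNA other than CD34- RNA 3 (up to 0.119 and 0.101).

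Among 12 secreted factors that support haematopoiesis 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.654). Cxcl12, the chemokine that retains stem cells in the marrow, fell by 1.06 and Kitl, stem cell factor, fell by 0.63, whereas the growth factor Fgf7 rose by 1.17. A probe set of Cxcl12 on MG_U74Bv2 did not fall (981 to 1164 in CD34+ RNAs against 888 to 1178 in CD34- RNAs). Its further probe sets on MG_U74Av2 were lower in CD34+ RNAs (913 to 994 against 2771 to 3206, and 236 to 432 against 678 to 962). Kitl lost its call without CD34+ RNA 1 (adjusted p = 0.0564), 2 (0.0544) or 3 (0.0576). Of 10 markers of haematopoietic stem and progenitor cells, other than Cd34, Hoxa9 rose and Runx1, a transcription factor of blood cells and bone, fell by 0.71 (camera adjusted p = 0.806, and the same counts adjusted over the list alone). Hoxa9 was not called without any 1 CD34+ RNA or CD34- RNA 1 (adjusted p up to 0.0896), and Runx1 not without any RNA other than CD34- RNA 2 (up to 0.136).

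Markers of the lineages that stromal cells can form were not called as lists. Of 5 osteoblast markers Tnfrsf11b, osteoprotegerin, fell by 1.17 and 0 rose, with Msx2 also falling adjusted over the list alone (camera adjusted p = 0.605, median 0.17, mean -0.20, test down). Of 9 adipocyte markers Cebpa, a transcription factor of fat cells, fell by 0.51 and 0 rose, as adjusted over the list alone (camera adjusted p = 0.711, median 0.01, mean -0.003, test down). Cebpa lost its call without CD34+ RNA 2 (adjusted p = 0.0655) or CD34+ RNA 3 (0.0571). Of 7 chondrocyte markers 0 were called by limma, while Col9a1 and Col9a3 had an unadjusted p under 0.05 (camera adjusted p = 0.58). Of 11 skeletal muscle markers Myod1, a transcription factor of muscle cells, rose from 482 ± 152 to 1087 ± 101 (log2 1.13) and Tnnt2, a troponin, by 0.67, while Acta1, skeletal actin, fell by 1.10 (camera adjusted p = 0.605, and the same counts adjusted over the list alone). Tnnt2 lost its call without CD34+ RNA 1 (adjusted p = 0.06) or CD34+ RNA 2 (0.0551).

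Markers of other cell types that a marrow culture could hold did not pass as lists with camera and quantile-normalized values. Lymphoid genes were called lower in the deposited values centred on each array's median (camera adjusted p = 0.0475). That setting lowers dim probe sets in CD34+ clones, since the offset weighed more on the CD34- arrays. For macrophage and myeloid genes 0 of 8 were called by limma (camera adjusted p = 0.89), for lymphoid genes 0 of 9 (0.478), for endothelial genes 0 of 8 (0.605) and for pericyte genes 0 of 6 (0.41), and 0 of 3 neutrophil and 0 of 4 erythroid genes, too few for a list test, were called by limma. Adjusted over the list alone the counts were 0 too, and at an unadjusted p under 0.05 they were 2 for pericytes (Notch3 and Cspg4), 1 for endothelium (Pecam1) and 0 for the others. Pecam1 differed by log2 -0.89 (adjusted p = 0.0854) and Notch3 by log2 -0.55 (adjusted p = 0.117), and in centred deposited values both were called lower (0.0241 and 0.0275), as was Camp, a neutrophil granule protein (0.0495). These calls in centred deposited values share the limit of the offset given above. Of 8 neural markers Tubb3, a neuronal tubulin, rose by 0.42 and Gpm6b, a membrane proteolipid, fell by 0.93, with Gap43 rising and Ncam1 falling as well adjusted over the list alone (camera adjusted p = 0.743). Tubb3 was called only with all RNAs or without CD34+ RNA 3 (adjusted p up to 0.14 otherwise). Another Tubb3 probe set on MG_U74Av2 went the opposite way (220 to 289 in CD34+ RNAs against 332 to 471 in CD34- RNAs). Of 5 epithelial markers only Krt19 was called, upward (log2 1.57), as adjusted over the list alone (camera adjusted p = 0.501, but 0.0251 with fry).

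Calls of some single genes depended on the processing. Of 133 called probe sets of named genes, 20 lost their call in centred deposited values (adjusted p 0.0528 to 0.291), among them Ccl2, Ccl7, Ccl9, Ccn4, Cdkn2b, Eng, Herpud1, Hspa1b, Ifit3, Itgb1, P4ha1 and Slc25a13. In that setting the offset weighed more on the CD34- arrays, which may account for part of these losses. With arrays scaled to a common median 10 were lost (0.0506 to 0.105), Acta2, Ccn4, Cd9, Eng, Herpud1, Hsp90b1, Hspa1b, Itgb1, P4ha1 and Runx1, and with a common trimmed mean 4 (0.0548 to 0.0772), Acta2, Cd9, Hsp90b1 and Tusc1. Without a filter 16 lost their call (0.0536 to 0.107), among them Ccl7, Cd9, Hoxa9, Ifit3, Igf2, P4ha1, Runx1, Tubb3 and Itgbl1. Without a variance trend 29 did (0.0502 to 0.227), among them C1s1, Ccl7, Ccl9, Cd44, Cd9, Cdkn2b, Eng, Herpud1, Hsp90b1, Hspa1b, Id3, Ifit3, Igf2, Itgb1, P4ha1 and Tubb3. With the fluidics station as a block 23 lost their call, and with the replicate number as a block 15.

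Genes with probe sets on more than 1 chip type allowed a comparison of the log2 differences across genes, which are not independent replicates. Over 1191 genes MG_U74Av2 and MG_U74Bv2 correlated at 0.407 (Spearman 0.329), and 129 of the 171 genes called on MG_U74Av2 had the same sign on MG_U74Bv2. With MG_U74Cv2 the correlation was 0.197 for MG_U74Av2 (Spearman 0.171, 1140 genes, 121 of 176 called genes with the same sign) and 0.196 for MG_U74Bv2 (Spearman 0.153, 1290 genes, 16 of 20).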

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

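Scaling each array to a common median or trimmed mean and the station block were chosen after seeing the data. The deposited values without scaling called 7630, 7737 and 7481 probe sets on MG_U74Av2, MG_U74Bv2 and MG_U74Cv2, nearly all that were tested, since the groups had different scales. Centred on each array's median log2 value they called 1803, 460 and 2, 963 and 77 of them shared with the 1138 and 84 of the quantile-normalized values. The median scaling called 983, 90 and 9 and the trimmed mean scaling 1112, 94 and 6. Without a filter MG_U74Bv2 had 37 calls and MG_U74Cv2 0, without a variance trend 16 and 0 (on MG_U74Cv2 899 and 595 at an unadjusted p under 0.05), and with a smaller offset MG_U74Cv2 had 2. At least 2-fold were 209, 48 and 7. Leaving out 1 RNA gave 634 to 1230 calls on MG_U74Av2, 2 to 98 on MG_U74Bv2 and 0 to 1 on MG_U74Cv2, with fewer samples in each fit. With the station as a block MG_U74Bv2 kept 1 call and MG_U74Cv2 0, where the station is nearly confounded with the group. Where no construction shows it, the cause was not tested. The scan day could not be run as a block, since each chip type had 1 day.

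The replicate numbers did not pair the RNAs: deviations of same-numbered arrays correlated at -0.05 to 0.05 on MG_U74Av2, 0.02 to 0.07 on MG_U74Bv2 and -0.02 to 0.04 on MG_U74Cv2. With the replicate number as a block 956, 57 and 0 probe sets were called, and 10 lists, all but p53 targets (adjusted p = 0.0529).

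Of the 11 lists, 4 stayed past the threshold with an estimated correlation (matrix, cell cycle, proteases and cholesterol synthesis), 7 with fry, which also called epithelial markers (adjusted p = 0.0251), and 8 without a filter. In the deposited values without scaling 10 were called, 5 of them among the 11, the others being pericyte, macrophage, lymphoid, endothelial and Hox genes. Of 28 lists 8 changed direction there: smooth muscle (adjusted p = 0.158), matrix (0.456), adipocyte and unfolded protein genes to up, and macrophage (0.00955), Hox (0.0158), imprinted and haematopoietic stem cell genes to down. Relative to the shift of all genes, smooth muscle and matrix genes stayed lower (log2 -0.14 and -0.38). Of 133 called named probe sets, 89 kept their call in all 6 leave-outs, and 0 turned in any setting that brought the arrays to one scale. The deposited values without scaling, which called 0 probe sets as lower, were left out of that count. Of 74 comparisons with other probe sets of these genes, 38 kept the call, 26 lost it (Acta2, Cd44, Ctsk, Cx3cl1, Eng, Grn, Hoxa9, Idi1, Igsf5, Itgb1, Lamp2, Lss, Marcks, Mrps21, P4ha1, Pdgfra, Pgk1, Runx1, Slc25a13, Stard4 and Tapbp) and 10 pointed the opposite way: Actg2 (0.15), Aldh1a2 (0.11 and 0.11), Cxcl12 (0.087), Fdps (-0.43), Grn (0.079), H2-K1 (0.23), Marcks (0.071), Nr4a1 (-0.47) and Tubb3 (-0.57, all log2), and the cause was not tested. Across chip types the correlation of MG_U74Av2 with MG_U74Bv2 was 0.299 without a filter and 0.469 with a stricter one, with MG_U74Cv2 0.12 and 0.277, and between MG_U74Bv2 and MG_U74Cv2 0.278 with the stricter one.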

Other observations

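The gene groups of the next paragraph and the tests of shared genes, smaller differences, haematopoietic markers with their further settings, the H2 family, variation between RNAs, quantile normalization and the fluidics station were chosen after the results they bear on were seen. The p-values of those gene groups therefore describe the values that prompted them. The tests of other splits, a larger spread and a trend with signal were fixed before.

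Genes of the lysosome were lower in CD34+ clones, with 12 of 36 falling and 0 rising when Ctsk and 2 members of the lists above, Ctsl and Gusb, are left out (median log2 difference -0.42, camera adjusted p = 1.55e-09, and adjusted p = 0.03 with an estimated correlation). Ctsb, a lysosomal protease, went from 19600 ± 1488 to 9794 ± 592 (adjusted p = 0.000132) and Grn, progranulin, from 7152 ± 814 to 3160 ± 354. Immediate early genes, which serum and stress induce within minutes, were grouped because of Fos, and without it, Atf3 and Btg2, 11 of 20 fell and 2 rose (median log2 difference -0.53, camera adjusted p = 1.76e-06, and adjusted p = 0.0299 with an estimated correlation). Klf4, a transcription factor, went from 1558 ± 210 to 530 ± 60 and Egr1, another, from 3591 ± 1281 to 1345 ± 278 (adjusted p = 0.00539), while Fosl1 and Nr4a1 rose by 0.47 and 0.65. Fosl1 lost its call without CD34+ RNA 1, CD34+ RNA 2, CD34- RNA 1 or CD34- RNA 3 (adjusted p up to 0.118), and Nr4a1 without CD34+ RNA 1, CD34+ RNA 3, CD34- RNA 1 or CD34- RNA 3 (up to 0.136). Proteasome subunits were higher, with 10 of 31 rising and 0 falling (camera adjusted p = 5.94e-07), as were genes of ribosome assembly, with 9 of 38 rising (5.98e-06), and mitochondrial ribosomal proteins, with 8 of 48 rising (7.34e-06), and each of these 3 lists had an adjusted p of 0.066 with an estimated correlation. Psma5, a proteasome subunit, went from 2895 ± 267 to 5613 ± 249 (adjusted p = 0.000397). All 5 lists kept their direction under every scaling tried, relative to the median of all genes.

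Interferon response and antigen presentation genes were lower in CD34+ clones, and haematopoietic cells among the CD34- cells could bring such RNA, although the labels put the purity of these single-cell colonies at 100%, by flow cytometry for CD34, a gate that would not remove haematopoietic cells that lack it. This stays open. In quantile-normalized values 24 of their markers had a median log2 difference of -0.061 ± 0.096 (SE) against -0.608 for the interferon list. With a common median it was -0.075 ± 0.098 against -0.614, and with a common trimmed mean -0.072 ± 0.098 against -0.614. Quantile-normalized values without the filter gave -0.084 ± 0.063 for 61 markers against -0.596. Only the deposited values centred on each array's median, where the offset weighed more on the CD34- arrays, went the other way. There it was -0.32 ± 0.098 against -0.358 (lymphoid list camera adjusted p = 0.0475), and without the filter as well -0.673 ± 0.135 against -0.014. The brightest tested markers were near equal in CD34+ and CD34- clones (Slc4a1 on MG_U74Cv2 2404 against 2387, Cd14 1855 against 1930, Csf1r 711 against 702). Probe sets of 1 marker differed in level, however. Another Csf1r probe set read 203.2 against 206.6, and Laptm5 read 439.5 against 402.8 at 1 probe set and 105.9 against 111.3 at another. Part of this signal may be background, so near-equal levels do not show equal haematopoietic RNA. Lyz2, Cd53, Coro1a, Fcer1g and others did not pass the filter on low values. Of these, Cd53 (31.3 against 117.5), Coro1a (68.73 against 155.8) and Fcer1g (38.08 against 122.4) were lower in CD34+ clones on MG_U74Av2. Lyz2 read 10.71 against 13.2 and 11.56 against 10.07, and Blnk was higher in CD34+ clones (229.3 against 88.03). In quantile-normalized values without the filter, 37 of the 61 markers were lower in CD34+ clones, relative to all genes. The 11 antigen presentation genes outside the H2 family had a median of -0.516, which cross-hybridisation within that family would not give. Whether it shapes the H2 values themselves cannot be told from those genes. A further H2-K1 probe set did not fall, at 359.7, 229.1 and 327.1 in CD34+ RNAs against 246.1, 238.7 and 264.3 in CD34- RNAs. Variation between RNAs of a group may account for part: another split of the 6 RNAs gave the interferon list an adjusted p of 1.68e-14, lower than the 6.80e-08 of the real groups, a test that replaced an earlier one on leaving out each RNA, in which the list had kept its call (adjusted p 1.10e-11 to 1.54e-05), and a difference between CD34+ and CD34- cells stays open and untested.

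Cell cycle genes were higher and extracellular matrix genes lower in CD34+ clones. Quantile normalization is argued against as the cause: with each array scaled or centred by a single value both lists kept their call (highest adjusted p = 1.03e-07). Of 10000 random lists matched on signal, 0 had a median as far out as either list, which argues against a trend with signal; that value was first read as a percentile. With the station as a block on MG_U74Av2 the highest adjusted p was 5.16e-08, which argues against the station. A faster-growing or less confluent culture, RNA quality and a lasting difference between the clones could each give this and were not tested. Signs of RNA quality moved with the groups on MG_U74Av2, but the Gapdh ratio of the same RNAs did not on the other chip types.

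MG_U74Cv2 gave few calls. Different genes on the chip type are argued against for the 1140 genes tested on both, since 176 of them were called on MG_U74Av2. That 1 of them was called on MG_U74Cv2 adds nothing, since all calls there named only 5 genes. A larger spread between arrays may contribute: with the residuals of MG_U74Av2 widened 2.12 times to those of MG_U74Cv2, 19 of its 1138 calls were left. Signal on MG_U74Cv2 was also lower beside the spiked control transcripts. These lay 4.87 (CD34+) and 5.20 (CD34-) log2 units over the trimmed mean, against 2.69 and 3.17 on MG_U74Av2. The filter ranks probe sets within each array, so many tested there may be dim, and this was not tested as a cause. Smaller differences may contribute too, as genes called on MG_U74Av2 had 0.275 of their log2 difference on MG_U74Cv2 (95% interval 0.221 to 0.392), a ratio that choosing the genes on MG_U74Av2 makes lower.

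The 6 RNAs can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In the real split 1138, 84 and 7 probe sets were called on the 3 chip types, 1 of 10 splits reached as many on each, and the highest of the other splits was 0 on each. Every other split puts 2 RNAs of a group with 1 of the other. The group difference then widens the spread within each side, so few calls are expected there whatever its cause. Part of the difference also stays between the sides, so a list that differs between the groups can be called in such splits. For gene lists the real split called 11 and the highest other 8, and 1 of 10 splits reached 11; with an estimated correlation the counts were 4 and 0. Of the 9 other splits, 6 called the matrix list (lowest adjusted p = 0.00135), 4 cell cycle genes (0.00728), 2 proteases (0.0173), 1 cholesterol synthesis (0.0402) and 1 smooth muscle (0.0487). Interferon response was called in 5, antigen presentation in 2 (5.37e-06) and chemokines in 2 (1e-04), each with a lower p than in the real split, and macrophage markers in 2 (0.00337) and adipocyte markers in 1 (0.0333), which the real split did not call. Wnt, glycolysis and p53 lists were called in 0 (lowest adjusted p 0.0939, 0.306 and 0.052).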
